A study of Rattus norvegicus with 10 samples.

How the data were processed

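Male F344/N rats, 5 to 6 weeks old at the start, received N,N-dimethyl-p-toluidine (DMPT) by corn oil gavage for 5 consecutive days, or the vehicle alone, per the labels. DMPT is an aromatic amine used as an accelerator in acrylic bone and dental cements. The 120 mg/kg/day group and the vehicle group are analysed here. Transitional epithelium of the nasal cavity was collected by laser capture microdissection, in which cells are cut from a tissue section under the microscope. Per the labels' protocols, RNA was amplified with the WT-Ovation Pico system, labelled with biotin and hybridised to arrays, and RNA was accepted above a set RNA integrity number. Part of the extraction protocol in the labels describes pooled samples of another kind, and its yields and purity values were not used here. Each of the 10 arrays came from a separately numbered animal, 5 per group. The labels state that animals shared cages; which animals did so is not given in the sources used here, so the arrays were treated as independent.

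The values deposited by the authors are log2 expression values per probe set, made with RMA (robust multi-array average) per the submitters' processing notes. RMA corrects the background, equalises the distributions of the arrays and summarises the probes of a probe set. The RMA software version and any probe filter are not given in the sources used here. The probe set names and control probe sets are those of an Affymetrix rat expression array. The table holds 31099 probe sets in 10 columns, 1 per animal, with array medians between 8.21 and 8.35. Arrays give no read depth, and their number limits the precision.

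Gene symbols came from the platform annotation supplied with the data. Of 31042 probe sets left after 57 control probe sets were set aside, 20826 had 1 symbol, 436 had several and 9780 had none; probe sets with several symbols or none were tested but not named. The Entrez identifiers of 20758 probe sets were found in the RefSeq gene table of assembly GRCr8, which changed 0 symbols and was used for names alone. No coordinates are given because the sources used here name no genome build. A gene was represented by the probe set with the highest mean over the 10 arrays, which gave 14217 genes, 4525 of them with more than 1 probe set.

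Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, intercept and treatment), on the deposited log2 values without a further filter. P-values were two-sided and adjusted by the Benjamini-Hochberg method over all 31042 probe sets, with a threshold of 0.05. Unless stated otherwise, values after ± are standard errors from this fit, and differences are log2 DMPT minus vehicle. The authors compared the groups with the ORIOGEN software at an FDR of 5%, per the series' design text. That software was not run; a permutation test of the SAM type with 100 label permutations was computed as an alternative.

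Before the data were examined, 30 gene lists were fixed, 6 of them as main lists. The lists covered stress responses, metabolism, proliferation, epithelial cell types and the other cell types that captured tissue can hold. They were tested with limma's camera at its preset inter-gene correlation of 0.01 and adjusted over the 30 lists, with camera at an estimated correlation and fry beside it. Camera compares a list with all other genes; fry asks whether the genes of a list move, on balance, in one direction. Counts of list members past the threshold are given over all probe sets and, in brackets where stated, adjusted over the list alone. A list score per animal is the mean log2 difference of the list's genes from the vehicle mean. Some genes belong to several lists; for example, 7 genes are shared by the xenobiotic metabolism list and the sustentacular and Bowman gland list.

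Genes were named by a rule fixed in advance. It took the 12 largest rises and 12 largest falls among called genes whose groups did not overlap, the 4 members of each main list and 2 of each other list with the smallest p, and a fixed panel of 14 genes, of which Hba-a1 was not measured under that name. These parts gave 95 genes. The genes Cyp1b1, Rprm, Tnf, Galnt6, Lyz2, Adcy3, Sec14l3, Cyp2g1, Cd37, RT1-Db1, RT1-Da, Ankrd37, Slc3a2, Phgdh, Sel1l, Manf, Asns, Herpud1, Gbp2, Psmd2 and Col1a1 were named after their values were seen.

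RNA quality was measured as the mean 3' minus 5' log2 difference of the GAPDH and beta-actin control probe sets. Spread among animals was the root mean square distance of an array from the mean of the other arrays of its group. Both were compared by two-sided exact permutation tests over the 252 labelings, for which the smallest possible p is 0.00794. The distances were computed once in the real groups and not again for each labeling. Arrays of a group share their reference arrays, so the p of the spread is only approximate. The fit was tested on simulated data with the real means and residual spreads and 200 changed probe sets among 31042, in 5 against 5 arrays. Limma recovered 25.4%, 80.6% and 98.5% of probe sets changed by 0.5, 1 and 2 log2 units, and 6.21% of its calls were false. The permutation test recovered 11.9%, 83.6% and 100% of them. The simulated noise was independent between probe sets, and fewer probe sets changed than were called in the data. These rates therefore need not hold for the data.

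Alternatives comprised filters on dim probe sets, renewed quantile normalization, median centring, a trended robust prior, array weights, the replicate number as a block, the array number and the RNA ratio as covariates, other tests, other probe sets per gene and the omission of each array. A covariate for the 3' bias of the bacterial poly-A spikes was added after the data were seen. Figures were drawn with matplotlib 3.10.9.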

Results

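The data describe the nasal transitional epithelium of rats given DMPT at 120 mg/kg/day for 5 days, set against rats given corn oil alone. The comparison asks which transcripts in this epithelium differed at the end of dosing. The groups held 5 arrays each, and pairs of arrays correlated at r between 0.959 and 0.992 over all probe sets. The first principal component held 41.0% of the variance and separated the groups. Vehicle replicate 2 lay apart on the second component (18.3% of the variance). It also had the highest score on the first, 63.8, with the other vehicle arrays between 15.1 and 32.1. Its mean correlation with the other vehicle arrays was 0.975.

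**Figure D1:**
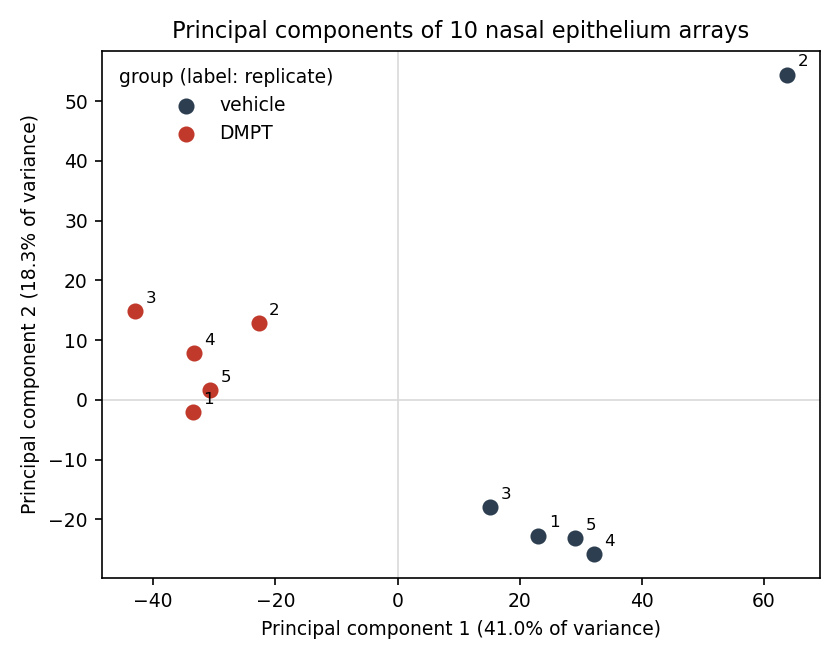
Scores of the 10 arrays on principal components 1 and 2 over 31042 probe sets, each point being an animal labelled with its replicate number. DMPT arrays have negative scores on the first component and vehicle arrays positive scores; vehicle replicate 2 has a second-component score of 54.4.

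After DMPT, transcripts of the glutathione and NRF2 response, of dividing cells and of squamous epithelium rose, and those of motile cilia fell. With an estimated correlation between genes, the adjusted p of their lists was 0.0183, 0.0875, 0.204 and 0.318, in that order. By fry, which asks a different question, it was 1.37e-06, 1.57e-04, 0.00182 and 0.0195. In the limma fit, 1975 of 14217 genes passed the threshold, 1013 of them higher and 962 lower. A change of at least 2-fold was found in 272 of the higher and 237 of the lower genes, and of at least 4-fold in 39 and 15. Over probe sets, 1668 were higher and 1783 lower, which is 11.1% of those tested. The groups did not overlap for 3426 probe sets, and chance gives 0.794% of those tested. Of 635 called genes with more than 1 probe set, 297 had another probe set called in the same direction and 0 had one called in the other. Without DMPT replicate 3, the counts fell to 1137 higher and 1022 lower, and without DMPT replicate 4 the lower count was 1147. With the RNA quality ratio as a covariate, 1328 were higher and 951 lower.

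The largest rise was that of Sprr1a, a precursor protein of the cornified envelope, at 4.81 ± 0.50 log2 units or 28.1-fold (adjusted p = 0.000162). Slc7a11, the cystine importer that supplies glutathione synthesis, rose by 4.12 ± 0.19, and the aldehyde reductase gene Akr7a3 by 3.90 ± 0.17 (adjusted p = 7.76e-07 for each). The cytochrome P450 gene Cyp3a9 rose by 3.51 ± 0.16, the actin-severing protein gene Scin by 3.87 ± 0.15 and the small Maf transcription factor gene Maff by 3.52 ± 0.28. C3h15orf48 rose 20.3-fold. The protease inhibitor gene Serpinb10, the surface protein gene Psca and the mucosal keratin gene Krt4 rose by between 2.94 and 3.30 log2 units. So did the calcitonin gene-related peptide gene Calcb and Ddit4l. Krt4 was dim with vehicle, with a mean of 5.95, below the lower quartiles of the arrays (6.37 to 6.51). The size of its rise is therefore uncertain.

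The largest fall was that of Gp2, which encodes a membrane-anchored glycoprotein, at -3.15 ± 0.37 log2 units or 8.87-fold (adjusted p = 0.000323). Ccno, needed for the multiplication of centrioles in multiciliated cells, fell by 2.84 ± 0.51 (adjusted p = 0.00459). C10h16orf89, Nrgn, Chad, Ermn and Azgp1 fell, with differences between -2.76 and -2.36 log2 units. Azgp1 was dim after DMPT, with a mean of 5.55, below the lower quartiles of the arrays (6.37 to 6.51). The size of its fall is therefore uncertain. Pik3c2g, the phenol sulfotransferase gene Sult1a1, the clock transcription factor gene Npas2, the trefoil peptide gene Tff3 and the ceruloplasmin gene Cp fell, with differences between -2.29 and -2.14. These 24 genes were taken from called genes whose groups did not overlap. Mup5, at -2.72 ± 0.72, was left out by that rule, and its call was lost without 7 of the 10 arrays in turn.

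**Figure D2:**
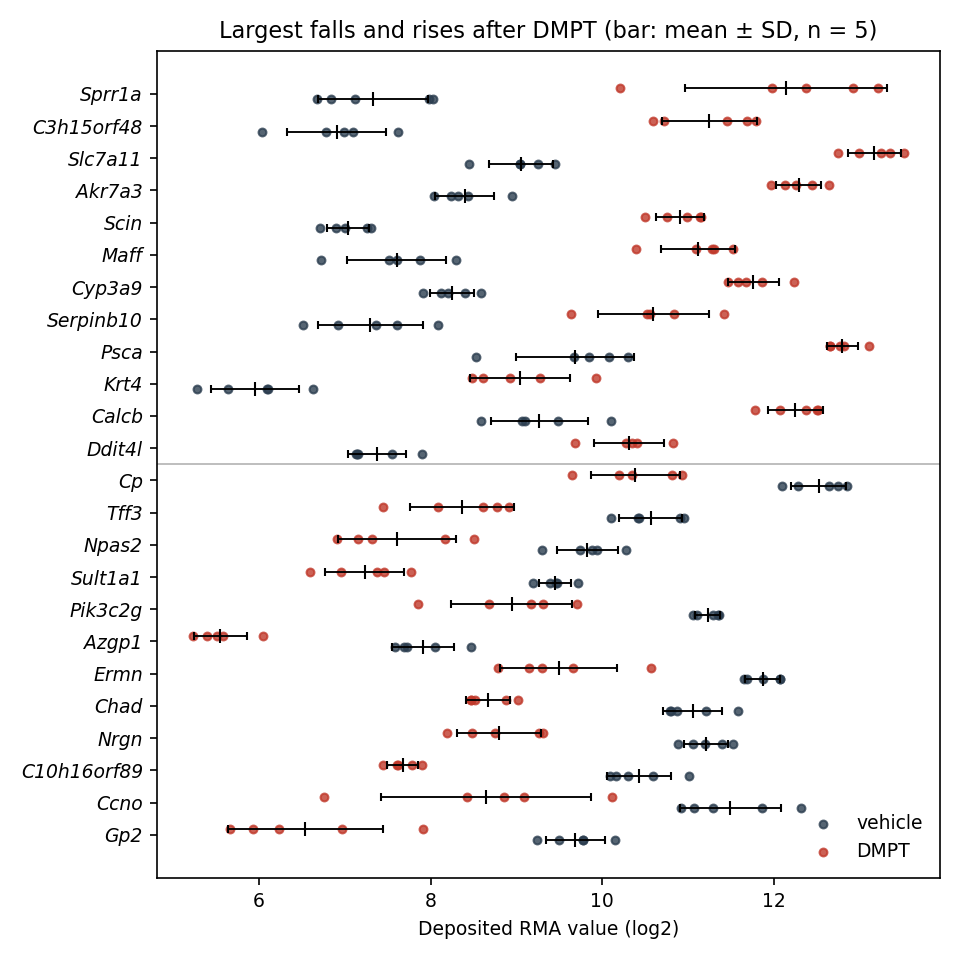
Deposited RMA values on the log2 scale (horizontal axis) for the 12 genes with the largest rise and the 12 with the largest fall among called genes whose groups did not overlap; points are animals, and bars give the mean ± SD (n = 5). Sprr1a, at the top, lay 4.81 log2 units higher after DMPT, and Gp2, at the bottom, lay at -3.15.

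Genes of the NRF2 and glutathione response rose as a group. Of 41 measured members, 33 were higher and 0 lower, or 35 and 0 adjusted over the list alone, and 8 did not pass. The mean difference was 0.90, the score was above all vehicle arrays in 5 of 5 DMPT arrays, and the list passed camera (adjusted p = 2.11e-26) and also camera with an estimated correlation (adjusted p = 0.0183). Both subunit genes of glutamate-cysteine ligase, the first enzyme of glutathione synthesis, rose, Gclm by 1.84 ± 0.12 and Gclc by 1.42 ± 0.10. The quinone reductase gene Nqo1 rose by 0.74 ± 0.089 (adjusted p = 0.000416) and the heme oxygenase gene Hmox1 by 0.94 ± 0.24 (adjusted p = 0.0261). Gpx2, a glutathione peroxidase of epithelia, had a difference of 0.26 ± 0.074 (adjusted p = 0.0465). Its mean was 14.2 with vehicle, where the highest values of the arrays lay between 14.6 and 14.9. Nqo1 reached 14.1 after DMPT. The size of a rise is uncertain so near the top of the range. The call of Gpx2 was lost without any single array other than vehicle replicate 2, with values from 0.24 to 0.27 over the omissions. The call of Hmox1 was lost without DMPT replicate 1 or vehicle replicates 1, 4 or 5, with values from 0.77 to 1.08.

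Genes of phase I and II xenobiotic metabolism went both ways, with 8 of 42 higher and 8 lower, or 8 and 9 adjusted over the list alone. Beside Cyp3a9, the alcohol dehydrogenase gene Adh7 rose by 0.72 ± 0.097. Beside Sult1a1, the P450 gene Cyp4a8 fell by 1.49 ± 0.17 and Cyp2a3, a P450 abundant in the nasal mucosa, by 0.50 ± 0.092 (adjusted p = 0.00542). Cyp2e1 differed by -0.26 ± 0.42 and Cyp1a1 by -0.19 ± 0.26, and neither passed the test. Without vehicle replicate 4 the difference of Cyp2e1 was -0.70 (adjusted p = 0.0929) and without vehicle replicate 1 it was -0.062; without DMPT replicate 1 that of Cyp1a1 was 0.017. The mean of the list was 0.023, its median -0.039 and its camera direction downward, with an adjusted p of 0.891. That mean ran from 0.0012 without DMPT replicate 2 to 0.051 without vehicle replicate 5. The counts were 5 higher without vehicle replicate 3, 5 lower without vehicle replicate 2, vehicle replicate 5 or DMPT replicate 5, and 5 and 3 with the RNA ratio as a covariate. Of 9 aryl hydrocarbon receptor targets, Nqo1, Aldh3a1 and Cyp1b1 rose and 0 fell (4 and 0 adjusted over the list alone), with a mean of 0.44 and a camera adjusted p of 0.0286. That list had an adjusted p of 0.266 with an estimated correlation and of 0.0561 without DMPT replicate 1; it was 0.0896 with array weights and 0.0721 with the RNA ratio as a covariate. Cyp1b1, named after its value was seen, lost its call without 7 of the 10 arrays in turn. Nqo1 and Nfe2l2 belong to both the aryl hydrocarbon receptor list and the NRF2 list, so the 2 lists are not separate evidence. Aldh3a1 rose by 1.04 ± 0.23; vehicle replicate 2 had a log2 value of 12.2 for it and the other vehicle arrays between 13.4 and 13.6. With the RNA ratio as a covariate the difference of Aldh3a1 was 0.81 and its adjusted p was 0.0815.

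Genes of the cell cycle and DNA replication rose together. Of 54 measured members, 48 were higher and 0 lower, or 51 and 1 adjusted over the list alone, with a mean of 0.95. The centromeric histone gene Cenpa rose by 1.69 ± 0.15, the midzone protein gene Prc1 by 1.23 ± 0.13, the mitotic kinase gene Plk1 by 1.14 ± 0.13 and the primase gene Prim1 by 0.89 ± 0.099. Mki67, the proliferation marker, rose by 0.88 ± 0.099 (adjusted p = 0.000268). The score was above all vehicle arrays in 5 of 5 DMPT arrays, and the list passed camera with an adjusted p of 2.57e-32; its adjusted p was 0.0875 with an estimated correlation. Of 25 genes of the p53 and DNA damage response, Phlda3 rose and Ercc5 and Rprm fell (1 and 2 adjusted over the list alone), and the camera adjusted p was 0.279. Cdkn1a, the p53-induced inhibitor of cyclin-dependent kinases, differed by 0.22 ± 0.11 (adjusted p = 0.245). Rprm did not pass without DMPT replicate 5 (adjusted p = 0.0529). The higher count of the p53 list was 2 without vehicle replicate 2 and 3 with the spike covariate.

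Markers of squamous and basal epithelium were higher. Of 45 measured members, 16 rose and 0 fell, or 22 and 1 adjusted over the list alone, with a mean of 0.54. Beside Sprr1a and Krt4, the nerve growth factor receptor gene Ngfr, a basal cell marker, rose by 1.96 ± 0.17 and the stratifin gene Sfn by 1.22 ± 0.16. The basal keratin gene Krt5 rose by 0.60 ± 0.11 (adjusted p = 0.00537). The list passed camera (adjusted p = 1.06e-07) with its score above all vehicle arrays in 5 of 5 DMPT arrays; its adjusted p was 0.204 with an estimated correlation.

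Genes of motile cilia were lower, with 30 of 46 members lower and 0 higher, or 42 and 0 adjusted over the list alone, and 46 of 46 differences below 0. The axonemal dynein heavy chain gene Dnah1 fell by 1.77 ± 0.33 and Dnah2 by 1.79 ± 0.39. Spef1, which encodes a microtubule-binding protein of the axoneme, fell by 1.14 ± 0.23 and the intraflagellar transport gene Ift57 by 0.92 ± 0.20. Foxj1, the transcription factor that switches on motile cilia genes, differed by -0.88 ± 0.25 (adjusted p = 0.0426). The mean of the list was -1.04, and 4 of 5 DMPT arrays scored below all vehicle arrays. Camera gave an adjusted p of 6.86e-16, and the adjusted p was 0.318 with an estimated correlation. The scores varied widely within groups, from -1.82 to -0.36 after DMPT and from -0.59 to 0.47 with vehicle. The number of lower members was 18 without vehicle replicate 1, 14 without vehicle replicate 2, 8 without DMPT replicate 5, and 9 without vehicle replicates 4 or 5 or DMPT replicates 3 or 4. It was 4 with the RNA ratio as a covariate, where the mean was -1.08 and Dnah2 had an adjusted p of 0.0564. The call of Foxj1 was lost without any of those 7 arrays, with values from -1.05 to -0.70.

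**Figure D3:**
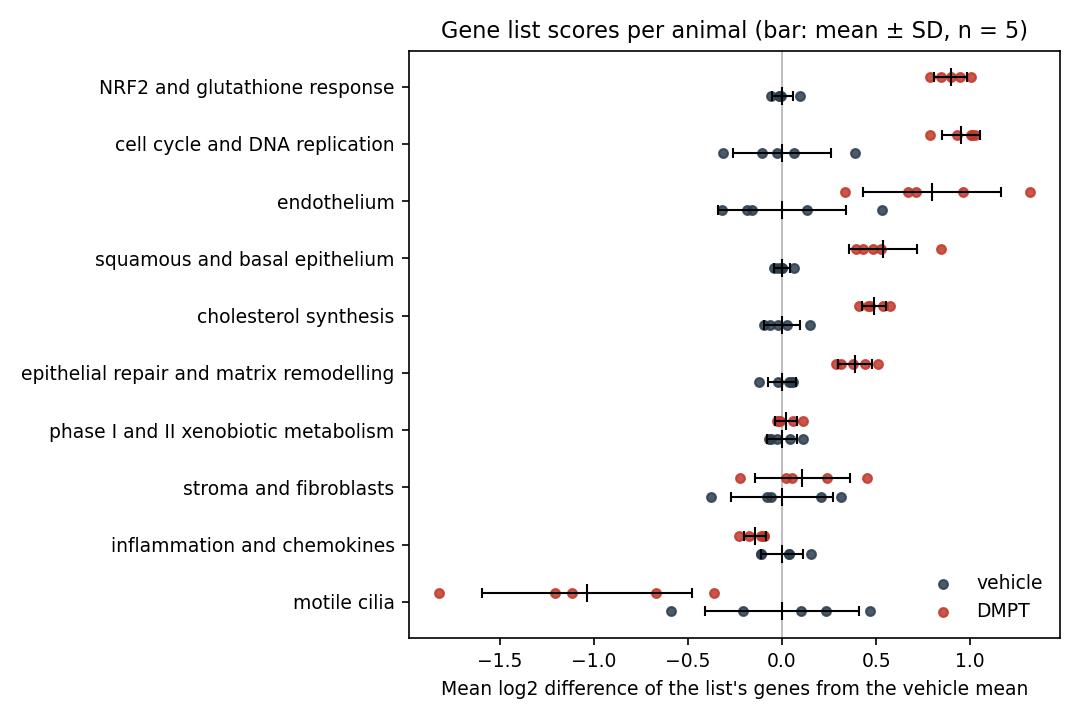
Score of each animal (points) on 10 gene lists, as the mean log2 difference of the list's genes from the vehicle mean (horizontal axis); bars give the mean ± SD (n = 5). The NRF2 scores of the DMPT arrays lie between 0.79 and 1.00, above all vehicle arrays, whereas the motile cilia scores run from -1.82 to -0.36 and overlap those of vehicle.

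Genes of inflammation and chemokines did not pass the test as a group (mean -0.14, camera adjusted p = 0.201), with 3 of 50 higher and 7 lower over all probe sets and adjusted over the list alone. Il1rn, which encodes the antagonist of the interleukin 1 receptor, rose by 1.76 ± 0.18 (adjusted p = 0.000133), and Il18 rose by 0.75 ± 0.14. Tnf was the other higher member (adjusted p = 0.0416), and its call was lost without any single array other than vehicle replicates 2 and 3. Beside Cp, the chemokine gene Ccl20 fell by 1.57 ± 0.28 (adjusted p = 0.00450). Il1b differed by -0.19 ± 0.14 and did not pass, with -0.10 without DMPT replicate 2 and -0.11 without vehicle replicate 5. The number of lower members was 3 without vehicle replicate 5 and 4 without vehicle replicate 1 or DMPT replicates 1, 3 or 4.

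Lists of other cell types in or near the captured tissue were measured beside those of the epithelium. Endothelial genes were higher, with 12 of 25 higher and 0 lower (14 and 1 adjusted over the list alone) and a mean of 0.80. Most were dim: 22 of the 25 lay below the median level of all probe sets. The adhesion molecule genes Pecam1 and Esam rose by 1.15 ± 0.17 and 1.19 ± 0.19. The endothelial list had a camera adjusted p of 1.06e-07 and an adjusted p of 0.303 with an estimated correlation. Its adjusted p by fry was 0.0161. The number of higher members was 5 without vehicle replicate 4 or DMPT replicate 3, 7 without DMPT replicate 1, and 3 with the RNA ratio as a covariate. The stromal list did not pass: Pcolce alone rose among 40, by 1.66 ± 0.15, the collagen gene Col1a1, named after its value was seen, differed by -0.10 ± 0.18 (from -0.24 to -0.0061 without each array in turn), and the camera adjusted p was 0.487. Fbln1 differed by 0.49 ± 0.16 (adjusted p = 0.0798), and passed without vehicle replicate 2 (0.60, adjusted p = 0.0216).

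Among 34 secretory and mucous cell genes, Galnt6 rose and 7 fell (3 and 9 adjusted over the list alone), among them Tff3 and the polymeric immunoglobulin receptor gene Pigr at -1.79 ± 0.15. The higher count was 3 without DMPT replicate 5 and with the RNA ratio as a covariate, and 2 without DMPT replicate 3. The camera adjusted p of that list was 0.0583, and the number of lower members was 4 without vehicle replicates 1 or 5, without DMPT replicates 1, 3 or 4, and with the RNA ratio as a covariate. The secretory list passed in 10 alternatives, among them fry (adjusted p = 0.0295) and the omission of DMPT replicate 2 (0.0293), vehicle replicate 2 (0.0478) or vehicle replicate 3 (0.0405). Of 19 nasal gland genes, Aqp5, Mup5 and Lyz2 fell and 0 rose, also adjusted over the list alone (camera adjusted p = 0.174). Their number was 1 or 0 without any single array other than vehicle replicates 2 and 3 and DMPT replicate 2. The nasal gland list passed without the dimmest quartile of probe sets (mean -0.61) and with the RNA ratio as a covariate (adjusted p = 0.0427). Among 16 genes of olfactory sustentacular and Bowman gland cells, Calcb rose and Cyp4a8, Ermn, Sec14l3, Cyp2a3 and Cyp2g1 fell, with the same counts adjusted over the list alone. The call of Cyp2g1 (-1.06, adjusted p = 0.0362) was lost without any single array other than vehicle replicate 3 and DMPT replicates 1 and 2, with values from -1.26 to -0.86. That list had a camera adjusted p of 0.0278, which was 0.266 with an estimated correlation, 0.0579 without vehicle replicate 1 and 0.0505 without DMPT replicate 3. Of 34 olfactory neuron genes, Reep1 fell by 1.10 ± 0.11, Gap43 by 0.79 ± 0.18 and Adcy3 rose (0 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.696). Another probe set of Gap43 differed by 0.046, and the call of Adcy3 was lost without any single array other than vehicle replicate 2.

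Of 55 leukocyte genes, 8 were higher and 4 lower (9 and 4 adjusted over the list alone; camera adjusted p = 0.279). The complement gene C1qc, expressed by macrophages, rose by 0.61 ± 0.11. The antigen presentation genes Cd74, at -0.46 ± 0.081, RT1-Db1 and RT1-Da and the B cell gene Cd37 fell. The calls of Cd37 and RT1-Da were each lost without 7 of the 10 arrays in turn and that of RT1-Db1 without 8. The higher count was 5 without vehicle replicate 1 or DMPT replicates 2 or 3. The lower count was 1 without vehicle replicates 1 or 5 or DMPT replicates 1, 2 or 5, and 2 without DMPT replicates 3 or 4. Of 16 neutrophil genes, Slfn4 and Mmp8 passed, the same adjusted over the list alone, and the camera adjusted p was 0.487. Slfn4 and Mmp8 each lost the call without 7 of the 10 arrays in turn. All 16 lay below the median level of all probe sets, and Mmp8 was near background, at 4.81 with vehicle. The list therefore says little about neutrophils. Tfrc, the transferrin receptor gene, was the higher member among 14 erythrocyte genes, at 1.39 ± 0.11; dividing cells of other kinds also use it, and Bpgm differed by 0.27 ± 0.088. Tnnt1 was the lower member among 25 muscle genes, but not without vehicle replicates 4 or 5 or DMPT replicate 5, and Casq1 differed by -0.87 ± 0.26, passing without DMPT replicate 5 (-1.09, adjusted p = 0.0121). Among 23 cartilage and bone genes Acp5 rose and Chad fell; the mean of that list was -0.0038, its median 0.063 and its camera direction downward. That mean was -0.21 without DMPT replicate 4 and 0.077 without DMPT replicate 2. The lower count of the cartilage list was 2 without DMPT replicate 1 or vehicle replicates 2 or 3. The camera adjusted p was 0.279 for erythrocytes (0.0327 by fry), 0.528 for muscle and 0.709 for cartilage. Adjusted over the list alone the counts were 1 and 0, 0 and 1, and 1 and 2.

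Cholesterol synthesis and epithelial repair were the other lists that passed camera at both correlations. Of 21 cholesterol synthesis genes, 12 rose and 0 fell (16 and 0 adjusted over the list alone), with a mean of 0.49 and adjusted p-values of 3.63e-08 and, with an estimated correlation, 0.0450. Sc5d and Dhcr7, enzymes of its last steps, rose by 1.06 ± 0.11 and 0.94 ± 0.12. Of 46 genes of repair and matrix remodelling, 10 rose and 0 fell (13 and 2 adjusted over the list alone), with a mean of 0.39 and adjusted p-values of 3.87e-05 and, with an estimated correlation, 0.0200. The growth factor gene Ereg rose by 2.89 ± 0.27 and the macrophage elastase gene Mmp12 by 1.62 ± 0.18.

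Of 31 hypoxia genes, 9 rose and Ankrd37 fell (12 and 3 adjusted over the list alone; camera adjusted p = 0.000192). The adrenomedullin gene Adm rose by 1.26 ± 0.11 and the hexokinase gene Hk1 by 1.25 ± 0.14; the list had an adjusted p of 0.0839 with an estimated correlation. The call of Ankrd37 was lost without any single array other than DMPT replicates 1 and 2, with values from -0.43 to -0.29. Of 26 immediate early genes, 8 rose and 0 fell (8 and 1 adjusted over the list alone), with Egr1 at 2.20 ± 0.33 and Klf4 at 1.04 ± 0.13. That list had a camera adjusted p of 0.00478 and an adjusted p of 0.372 with an estimated correlation. Of 36 apoptosis regulators, 9 rose and 0 fell (10 and 2 adjusted over the list alone; camera adjusted p = 0.000925), and the adjusted p was 0.0887 with an estimated correlation. The proapoptotic gene Bcl2l11 rose by 1.40 ± 0.11 and the receptor gene Tnfrsf12a by 1.41 ± 0.11. The higher count was 5 without DMPT replicates 3 or 4.

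Of 37 genes of the unfolded protein response, Dnajb9, Slc3a2, Phgdh, Sel1l and Manf rose and Nupr1, Asns and Herpud1 fell (9 and 3 adjusted over the list alone). Nupr1, a stress-induced regulator, fell by 1.05 ± 0.14 and the chaperone gene Dnajb9 rose by 0.47 ± 0.091. The call of Manf was lost without any single array other than vehicle replicates 2 and 5 and DMPT replicate 5 (values from 0.36 to 0.46), and that of Herpud1 without vehicle replicates 4 or 5 or DMPT replicates 1, 3, 4 or 5 (values from -0.43 to -0.33). The camera adjusted p was 0.0222, and it was 0.379 with an estimated correlation; the higher count was 9 without vehicle replicate 2. That list had an adjusted p of 0.0710 with the probe sets below the median level left out and of 0.0580 with the most variable probe set per gene. Of 32 proteasome genes, Psme4, Psmd3 and Psmd2 rose (2 and 0 adjusted over the list alone), by 0.33 ± 0.078, 0.35 ± 0.086 and 0.25 ± 0.072. The call of Psmd2 was lost without any single array other than vehicle replicate 2 (values from 0.24 to 0.27), that of Psmd3 without DMPT replicates 2 or 5 (values from 0.32 to 0.40) and that of Psme4 without DMPT replicate 3 (adjusted p = 0.0532). The proteasome list had a camera adjusted p of 8.76e-05 and an adjusted p of 0.126 with an estimated correlation. Its higher count was 6 without vehicle replicate 2 and 1 without DMPT replicates 2, 3 or 5, and another probe set of Psme4 differed by -0.026. The proteasome score of vehicle replicate 2 was -0.21, below those of the other vehicle arrays (0.022 to 0.10).

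The remaining lists did not pass the test. Bag3 and Hspe1 rose among 19 heat shock genes (2 and 0 adjusted over the list alone; camera adjusted p = 0.271). Ifit2, at 0.75 ± 0.11, and Gbp2 rose and Ifi27, at -0.42 ± 0.085, fell among 42 interferon response genes (1 and 1 adjusted over the list alone). The mean of that list was 0.015, its median -0.016 and its camera direction downward (adjusted p = 0.736). That mean was -0.10 without DMPT replicate 4 and 0.079 without DMPT replicate 5, and Gbp2 lost its call without 7 of the 10 arrays in turn. The higher count of the interferon list was 3 without vehicle replicate 5, and its lower count was 2 without vehicle replicate 3 or DMPT replicate 4. Among 46 respiratory chain genes Ndufb6 passed at 0.32 ± 0.093 (0 adjusted over the list alone), a call lost without 8 of the 10 arrays in turn, and Ndufv2 differed by 0.21 ± 0.078 (camera adjusted p = 0.0820). The respiratory chain list passed with median centring and without vehicle replicate 5 (adjusted p = 0.0182). None of 30 ribosomal protein genes passed, also adjusted over the list alone; Rps24 differed by 0.12 ± 0.075 and Rplp0 by 0.28 ± 0.19 (camera adjusted p = 0.145). The difference of Rplp0 rested on vehicle replicate 2, at 12.9 against 13.95 to 13.99 in the other vehicle arrays, and was 0.078 without it. The ribosomal score of vehicle replicate 2 was -0.34, whereas the other vehicle arrays lay between 0.050 and 0.11.

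The RNA quality ratio, higher where RNA is more degraded or amplification more biased to the 3' end, was 1.10 ± 0.19 after DMPT and 1.28 ± 0.13 with vehicle (SD, n = 5 each). The difference of -0.18 had an exact permutation p of 0.143. The GAPDH controls in this ratio themselves rose after DMPT, by 0.46 (3') and 0.79 (5') log2 units. The beta-actin controls differed by 0.18 (3') and 0.21 (5') and did not pass the test. The ratio, also where it serves as a covariate, may therefore not measure RNA quality alone. The mean distance from the own group was 0.261 ± 0.020 log2 units after DMPT and 0.336 ± 0.087 with vehicle (SD, n = 5 each). The exact permutation p was 0.0238, but distances within a group are not independent, so it does not establish a difference in spread. This difference shrank to -0.028 (exact permutation p = 0.0952) without vehicle replicate 2. Its exact permutation p was also above the threshold without DMPT replicate 2 (0.0873), 3 (0.0873), 4 (0.127) or 5 (0.119).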

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

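The test of the control probe sets and the weighing of vehicle replicate 2 were chosen after the data were seen. Each group of 5 was searched for an array far from the rest, with the gap to its nearest neighbour divided by the range of the group and set against Dixon's critical value for 5 samples. Of 256 groups tested, 14 held an array beyond that value, where chance gives about 1 in 20, or 12.8.

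Vehicle replicate 2 accounted for 5 of the 14. Its distance from the other vehicle arrays was 0.491 log2 units, against 0.282 to 0.308 for the others. Its log2 value was 12.2 for Aldh3a1 and 12.9 for Rplp0, and its scores were -0.21 on the proteasome list and -0.34 on the ribosomal protein list, each below the other vehicle arrays.

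A candidate explanation for vehicle replicate 2 is a stronger 3' bias in amplification. The mean 3' minus 5' log2 difference of the bacterial poly-A spikes, which are added as intact RNA, was 3.33 in this array and 1.70 to 2.44 in the other 9. A treated sample labelled as vehicle is argued against by its NRF2 list score of -0.016, where the DMPT arrays lay between 0.787 and 1.00. Other captured tissue stays open: this array lay outside the other 4 vehicle arrays on 5 of 13 cell type lists, against 5.2 expected of any vehicle array, and its largest gap was 0.660 of their range (neutrophils). No biological explanation was tested.

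The other arrays far from their group were scattered. Ccl20 had a log2 value of 7.07 in DMPT replicate 5, Mup5 7.30 in DMPT replicate 2, and Sc5d 12.4 in DMPT replicate 3. Prim1 had 9.57 and Cyp2e1 5.92 in vehicle replicate 4, and Krt5 had 12.9 in vehicle replicate 1. The cartilage and bone score was 0.83 in DMPT replicate 4, the other DMPT arrays lying between -0.33 and -0.12, and the muscle score was -0.15 in vehicle replicate 1. The distance of DMPT replicate 1 from its group was 0.297, against 0.250 to 0.253 for the other DMPT arrays.

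Among the control probe sets, which no comparison used as genes, 5 differed between the groups after adjustment over the controls. The hexokinase controls were higher after DMPT by 1.38 (3'), 1.24 (5') and 1.15 (middle) log2 units, beside 1.25 ± 0.14 for the probe set of Hk1. The GAPDH controls were higher by 0.46 (3', adjusted p = 0.00363) and 0.79 (5', adjusted p = 0.0233).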

How the results depend on the processing

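Of the alternatives, the spike covariate was chosen after the data were seen. The NRF2 list kept its direction and call under every alternative run, and the xenobiotic metabolism and inflammation lists stayed without a call in all of them. Against a fold change of 1.2, 536 probe sets were higher and 354 lower. The lower count was 951 with the RNA ratio as a covariate and 1118 with 1 probe set per gene, where fewer are tested. With an estimated correlation, the cell cycle list (0.95, adjusted p = 0.0875) and motile cilia (-1.04, adjusted p = 0.318) were no longer past the threshold. The same held for squamous and basal epithelium (0.54, adjusted p = 0.204). The shifts are the same by construction. By fry, which asks a different question, these lists passed, with adjusted p-values of 1.57e-04, 0.0195 and 0.00182, in that order. Without each array in turn, 1137 to 2130 probe sets were higher and 1022 to 1886 lower, the lowest without DMPT replicate 3 and the highest without vehicle replicate 2.

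The difference in spread ran from -0.108 to -0.028 without each array in turn, and was -0.0886 (exact permutation p = 0.0556) without the dimmer probe sets; the cause was not tested. The RNA ratio difference ran from -0.231 to -0.125 without each array in turn, and was -0.332 with GAPDH alone, -0.031 with beta-actin alone and -0.294 with 3' minus middle; the GAPDH controls themselves rose. Among named genes, another probe set of Gap43 gave 0.046 (adjusted p = 0.803) and another of Psme4 -0.026 (adjusted p = 0.902); the cause was not tested. Named genes, with those chosen later, lost a call in 83 results of the other alternatives and gained one in 23; 28 of the losses came with the RNA ratio. Without single arrays, 178 calls were lost and 7 gained.

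The replicate numbers were not taken as pairs in the main fit. Same-numbered arrays deviated with correlations of 0.074, 0.216, 0.234, -0.067 and -0.012. The highest correlation with a vehicle array of another number was 0.153, 0.119, 0.021, 0.055 and 0.107, so pairing is not excluded for replicates 2 and 3. With the replicate block, 1545 probe sets were higher and 1825 lower. There the higher count went from 3 to 0 for proteasome genes and from 1 to 3 for stroma, and the lower count from 4 to 1 for leukocytes; other counts up to 10 moved by at most 1. Array weights gave 2280 and 2238, the permutation test 1437 and 1582, the spike covariate 2313 and 2364, and median centring 1963 and 1535. With the dimmer probe sets left out the neutrophil list gave no value. Arrays give no depth; dim probe sets lie near background.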

Other observations

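The gene groups of the following 2 paragraphs, the spike covariate, the bounds set for both covariates and the tests of captured tissue were chosen after the data were seen. Of 9 measured regulators of multiciliated cell differentiation, 6 fell, 0 rose and 3 did not pass, namely Plk4 at 0.53 ± 0.19, Rfx2 at -0.74 ± 0.23 and Cep152 at -0.43 ± 0.20. Plk4 passed without vehicle replicate 2 (0.69, adjusted p = 0.0145), and Rfx2 without vehicle replicate 1 (-0.85) or 3 (-0.90). Beside Ccno and Foxj1, Myb fell by 1.18 ± 0.19, the deuterosome gene Deup1 by 1.60 ± 0.31, Gmnc by 1.72 ± 0.49 (adjusted p = 0.0443) and Rfx3 by 0.56 ± 0.15. The calls of Gmnc, Rfx3 and Foxj1 were each lost without 7 of the 10 arrays in turn, with values from -2.01 to -1.25 for Gmnc and from -0.66 to -0.44 for Rfx3. Among 6 measured ligands of the epidermal growth factor family, Ereg, Areg (1.92 ± 0.23) and Hbegf (0.69 ± 0.16) rose and Egf fell by 0.89 ± 0.15. Hbegf did not pass without DMPT replicate 3 (adjusted p = 0.0510). Areg and Hbegf were dim, with vehicle means of 4.73 and 5.24, near background, so the size of their differences is uncertain.

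Of 7 measured genes of iron handling, Tfrc, the iron exporter gene Slc40a1 (1.31 ± 0.17), Slc11a2 (0.65 ± 0.16) and Aco1 (0.48 ± 0.12) rose and Cp fell. Slc11a2 lost its call without 5 of the 10 arrays in turn and Aco1 without DMPT replicates 2 or 3. Of 17 genes of the circadian clock, Nfil3 rose by 1.03 ± 0.21 and Npas2, Nr1d1 (-0.81 ± 0.10) and Per1 (-0.67 ± 0.15) fell. The other 13 did not pass, among them Bmal1 at -0.22 ± 0.18, Clock at 0.11 ± 0.088 and Per2 at 0.17 ± 0.15.

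The lower motile cilia genes were set against technical explanations. The shift was -1.08 with the RNA ratio and -1.02 with the spike ratio as a covariate, against -1.04. These values argue only against a cause that follows either ratio from array to array. The spikes are added as intact RNA and do not measure degradation of the sample. The RNA ratio rests in part on the GAPDH controls, which themselves rose after DMPT. RNA degradation as a cause therefore stays open. The members called nevertheless went from 30 to 4 with the RNA ratio, where the median standard error of members rose from 0.319 to 0.384. Dilution by captured stroma predicts a higher stroma score, which differed by 0.11 (exact permutation p = 0.540), with scores from -0.23 to 0.45 after DMPT and from -0.38 to 0.31 with vehicle; this spread leaves it open. Dilution by more captured squamous epithelium or vessels also stays open, since the squamous and basal list (0.54) and the endothelial list (0.80) rose. That dilution, fewer ciliated cells and less ciliary RNA per cell could each underlie the shift as hypotheses and were not tested.

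The higher endothelial genes were set against the same explanations, with the same limits of both covariates. Their shift was 0.811 with the RNA ratio and 0.783 with the spike ratio as a covariate, but the members called went from 12 to 3 with the RNA ratio, where the median standard error rose from 0.214 to 0.242. A rise no larger than that of the stromal genes is argued against by the endothelial minus stroma score, which rose by 0.69 (exact permutation p = 0.00794, the smallest possible). More captured connective tissue stays open, since the stroma score varied widely within groups. Col1a1, at 13.3 with vehicle, is bright and most endothelial genes are dim, so equal log2 changes cannot be assumed. A drift of dim probe sets is argued against by 0 of 10000 random lists matched on mean signal with a mean as high, the highest being 0.389. Random lists do not share the correlation between the endothelial genes, estimated at 0.465, so this count gives no p-value. More vessels in the captured tissue, or more endothelial RNA, could underlie the shift as a hypothesis; neither was tested.

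Other splits of the 10 arrays bear on chance, with 100 splits drawn and the real one included. For the 1668 higher and the 1783 lower probe sets, 1 split each gave as many, the highest other count being 0. For the shifts of the NRF2 list (0.90, highest other 0.618), the cell cycle list (0.95, 0.792) and the squamous and basal list (0.54, 0.405), 1 split each gave as large a value. For motile cilia (-1.04), 2 splits did, the highest other size being 1.13, above the real one. The adjusted p with an estimated correlation was 0.0875 for the cell cycle list, 0.204 for the squamous and basal list and 0.318 for motile cilia. All of these passed the 5% level of the splits, which was not adjusted over the results. For motile cilia another split gave a larger shift. At an unadjusted level, 100 splits do not exclude chance for any of these results. The level was not passed by the xenobiotic metabolism list (0.023, 61 splits, highest other 0.0996) or the inflammation list (-0.14, 7 splits, highest other 0.150).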
